A study of Mus musculus with 8 samples.

How the data were processed

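RNA of subcutaneous fat from 8 C57BL/6J mice was isolated with on-column DNase digestion, enriched for poly(A), made into libraries with a kit that does not mark strand, and sequenced, per the labels' protocols. The submitters' processing notes name FastQC, Bowtie2, edgeR and the mouse build mm9, with no role or version; the counter and annotation are not given in the sources used here. The authors deposited raw read counts per Ensembl gene and library, and a table of 1 comparison with a log2 fold change, a log2 mean expression, a p-value and an adjusted p-value per gene. The deposited counts are whole numbers and were not normalized. The deposited log2 values and p-values carry edgeR's column names, per the file headers. No coordinates are printed, since the annotation at hand is of another build; neighbours of genes were taken from GENCODE M21.

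The groups and replicate numbers were taken from the sample titles, and each column was matched to a sample by its mouse label. All 18022 genes of the table have at least 8 reads in total, and in each the second-highest CPM is at least 1.04, so low genes had been removed before deposit. There were 98 genes without a symbol, and 236 share a symbol with another; a shared symbol was given to the identifier with more reads. Genes that overlap were each given the shared reads: 46 genes with over 200 reads have counts identical to another gene, and Ube2c and Tnnc2, which overlap on opposite strands, had 306 and 308 reads in KO1 and 37 and 34 in KO3. Values of such genes are uncertain. The smallest chi-square per gene between libraries of a label was 4.45, over genes with at least 20 summed reads, so no library was counted as a copy of another. Y-linked genes had reads in all 8 libraries.

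Libraries held between 2617755 and 2873457 reads. The common dispersion was 0.0337, a biological coefficient of variation of 18.4%. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr (14556 genes tested), a robust fit and Benjamini-Hochberg adjustment at 0.05, with the label as the only term. Standard errors are the log2 fold change over the root of the F statistic, and intervals are 95%. CPM values are TMM-scaled. Single values were compared by exact permutation of the labels, on log2 CPM with a pseudocount of 0.5 for genes. On 14556 simulated genes with 200 changed, drawn from the means, library sizes and dispersions of these 8 libraries, the quasi-likelihood test recovered 11.9% of the genes changed 1.5-fold, 62.7% of those changed 2-fold and 93.9% of those changed 4-fold, with 3 false calls. With no gene changed it called 0 genes, and the exact test with one common dispersion called 83. The simulation with 200 changed genes also raised a small list of other genes, which were counted neither as recovered nor as false calls. The simulated genes were drawn independently, and the 200 were chosen only from genes above a minimum mean count. These figures therefore need not hold for real libraries, whose genes move together.

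Before the data were examined, 47 gene lists were fixed, and 39 had at least 5 tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, then with an estimated correlation and with fry. Named were the protein kinase D genes and Pkd1; the genes past the threshold with the largest change and no overlap, of which there were 0, and therefore the 4 per direction with the smallest p; 15 adipocyte genes; and from each list described up to 4 of the members with the smallest p, of which a few are not printed here. Described are lists called by camera, lists with a member past the threshold adjusted over the list alone, and lists on the study's question. The adjustment over the list alone was made within each list and was not corrected for the number of lists. There were 6 lists with such a member, and for single members past it chance is not excluded. Marker lists for liver, small intestine and brain, and marker sums without the gene that contributes most, were chosen after the data were seen.

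The alternatives were other scaling factors, other count filters, DESeq2 1.42.0, edgeR's likelihood ratio test, limma-voom with sample weights, a fit without the robust option, an adjusted p of 0.1, the replicate number as a block, 1 surrogate variable (sva 3.50.0), lymphoid or muscle marker levels as a covariate, and each library left out. Chosen after the data were seen were an exact test with one common dispersion and fits without WT2 and KO1 and without KO1, KO2 and KO4. A fit with sex as a term was not run.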

Results

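Poly(A) RNA of mouse subcutaneous fat was sequenced in 8 libraries, 4 labelled as floxed controls (WT) and 4 labelled as carrying an adipocyte deletion of Pkd1 (KO), each from its own mouse. Pkd1 is here the study's name for protein kinase D1, whose gene symbol is Prkd1; the gene with the symbol Pkd1 encodes polycystin 1. The libraries held between 2617755 (WT2) and 2873457 (KO2) reads over 18022 genes, and a letter code with a number, such as KO3, names a library by its label and replicate. Scd1, the stearoyl-CoA desaturase of fat, took between 7.64% and 10.3% of the reads of a library.

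The targeted gene was not lower in the libraries labelled KO. Prkd1 (ENSMUSG00000002688) stood at 30.1 ± 3.19 CPM (counts-per-million reads; SD, n = 4) in the libraries labelled WT and at 31.4 ± 4.71 CPM in those labelled KO. It had 88, 72, 94 and 73 reads in WT1 to WT4, and 71, 108, 84 and 94 reads in KO1 to KO4. The log2 fold change was 0.06 with a standard error of 0.15 and a 95% interval from -0.26 to 0.39 (edgeR quasi-likelihood test, adjusted p = 1; exact two-sided permutation p = 0.657). The sign of this value turned with skeletal muscle markers as a covariate (-0.105) and without KO2 (-0.024). The counts cover the whole gene and the whole tissue, so they include reads from exons outside the deleted part and from cells other than adipocytes; which exons were removed is not given in the sources used here. The counts therefore did not check the labels, and every direction below is one between libraries labelled KO and libraries labelled WT. Prkd2 and Prkd3, the other kinases of the family, had log2 fold changes of 0.12 ± 0.14 and 0.09 ± 0.15 (SE), and Pkd1 had 0.00 ± 0.13.

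**Figure D1:**
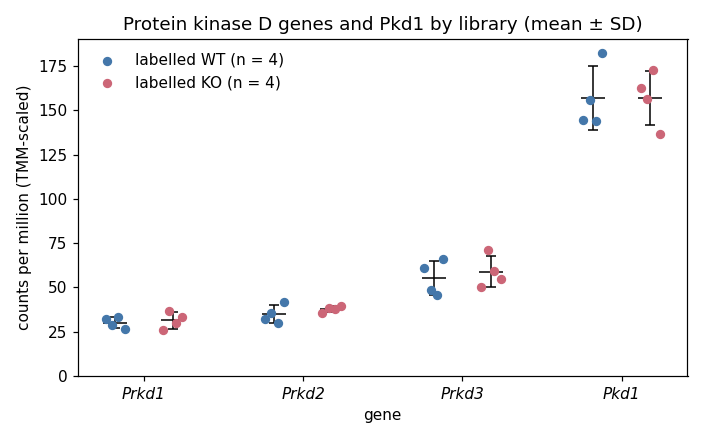
CPM (linear axis) of Prkd1, Prkd2, Prkd3 and Pkd1 in each of the 8 libraries, by label; points are libraries, black lines the mean and SD of 4. Prkd1 lies between 25.9 and 36.8 CPM in the libraries labelled KO and between 26.4 and 33.4 CPM in those labelled WT.

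The comparison of the labels asks which transcripts of subcutaneous fat differ when protein kinase D1 is deleted in adipocytes, a deletion that the study's title links to higher energy dissipation. No single gene passed the threshold. The nearest were Eif4a2, a translation initiation helicase, at 136 ± 14.9 CPM in libraries labelled WT and 229 ± 31 CPM in those labelled KO (1.69-fold, n = 4 each), and genes of skeletal muscle such as Mb, the oxygen carrier myoglobin, at 48.8 ± 7.37 and 104 ± 29.5 CPM. Thermogenic, beige and lipid-synthesis genes had values on both sides of 0. Of 14556 genes tested, 0 were higher and 0 were lower at an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.539. At an unadjusted p under 0.05 there were 653 genes, 395 with higher and the others with lower values in libraries labelled KO, where 727.8 would come by chance. Other tools gave more: DESeq2 called 45 higher and 6 lower, and edgeR's likelihood ratio test 30 and 4, while limma-voom with sample weights called 0 and 0. Without KO3, 50 genes passed as higher and 0 as lower. Of 72 genes chosen by the naming rule with a log2 fold change, 39 moved by over 1.5 times or turned sign in at least 1 of the fits that leave out a library. This count includes genes near 0, and of the 55 with a size of at least 0.2, 22 moved or turned. The groups did not overlap for 424 tested genes, or 2.91%, and chance gives 2.86% for 4 against 4.

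Among the genes with the smallest p, Eif4a2 (ENSMUSG00000022884) had a log2 fold change of 0.75 ± 0.13 (SE), with 346 to 395 reads in libraries labelled WT and 533 to 713 in those labelled KO. It passed over all genes with DESeq2, the likelihood ratio test and 1 surrogate variable, and in the authors' deposited table, where its adjusted p was 0.0143. In the main fit its adjusted p was 0.54 over all genes and 0.00043 adjusted over the list alone. The list was the genes beside Adipoq, fixed before the data were examined. That list had 6 tested members, 1 of them past the threshold adjusted over the list alone, 0 over all genes, and a median log2 fold change of -0.07 (camera adjusted p = 0.72). Kng2 of the same list had -0.28 ± 0.16 and Adipoq, the adipokine adiponectin, -0.12 ± 0.19. Adssl1, a muscle adenylosuccinate synthase, had 1.72 ± 0.33 and Zfp949, a zinc finger gene, 1.01 ± 0.20, both with an adjusted p of 0.54. On the lower side, Cldn15 had -0.69 ± 0.13 and Htra1, a secreted protease, -0.58 ± 0.12 (adjusted p = 0.54 for both). Ighm, the IgM heavy chain, had -0.91 ± 0.21 and Apoc2, an apolipoprotein made in liver, -1.91 ± 0.46 (adjusted p = 0.91 for both). Apoc2 had 49, 41 and 39 reads in WT1, WT2 and WT4, where liver or small intestine markers were high. It had 11 reads in WT3, inside the range of 4 to 15 in the libraries labelled KO.

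**Figure D2:**
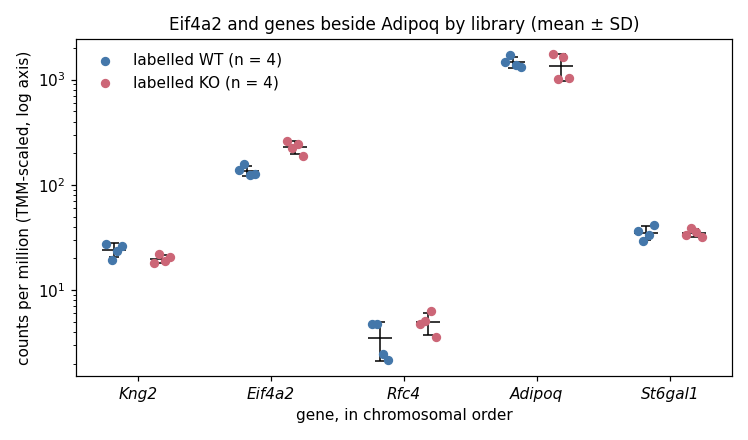
CPM (log axis) of Eif4a2 and of genes near it in chromosomal order, in each of the 8 libraries by label; points are libraries, black lines the mean and SD of 4. Eif4a2 lies between 188.8 and 259.8 CPM in the libraries labelled KO and between 122.8 and 156.2 CPM in those labelled WT, and the ranges of the other genes overlap.

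Skeletal muscle markers were the gene group furthest from 0. All 23 tested members had positive log2 fold changes, with a median of 2.84. Of these, 0 passed over all genes in the main fit and 21 rose when adjusted over the list alone. Myh1, Myh2, Eno3 and Mb passed over all genes with DESeq2, with the likelihood ratio test and without KO3. The group passed camera with a preset correlation (adjusted p = 5.9e-38), and did so with each library left out (largest adjusted p 1.9e-27, without KO4), but not otherwise (adjusted p = 0.32 with an estimated correlation, fry adjusted p = 0.42). Myh2 had a log2 fold change of 4.76 ± 0.92, Myh1 5.02 ± 1.06, Eno3 2.32 ± 0.53 and Mb 1.09 ± 0.20. The libraries differed within a label. The summed muscle markers stood at 3739 CPM in KO1, 2353 in KO2 and 4243 in KO4, but at 499.2 in KO3, inside the range of 156.1 to 669.2 CPM in the libraries labelled WT (exact two-sided permutation p = 0.0571; 4 against 4 can reach 0.0286). Of the 23 markers, KO3 lay inside the range of the libraries labelled WT for 19 and above it for 4, which are Myh1, Myh2, Mb and Eno3, the members named here for their small p.

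Other lists held members that are also abundant in muscle. Of 19 glycolysis genes, 0 passed over all genes and 2 rose adjusted over the list alone, Pfkm with a log2 fold change of 1.10 ± 0.26 and Eno3; the list's median was 0.01 (camera adjusted p = 0.66). Of 12 smooth muscle and pericyte markers, 1 rose adjusted over the list alone, Des at 2.10 ± 0.50, and Lmod1 had 0.54 ± 0.24. The list median was 0.10 (camera adjusted p = 0.27, and 0.92 with an estimated correlation). With the preset correlation the list passed as higher without KO1 (adjusted p = 0.0088). Pfkm had its 2 highest values in KO1 and KO4 and Des in KO1 and KO4, the libraries with the highest muscle sums.

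**Figure D3:**
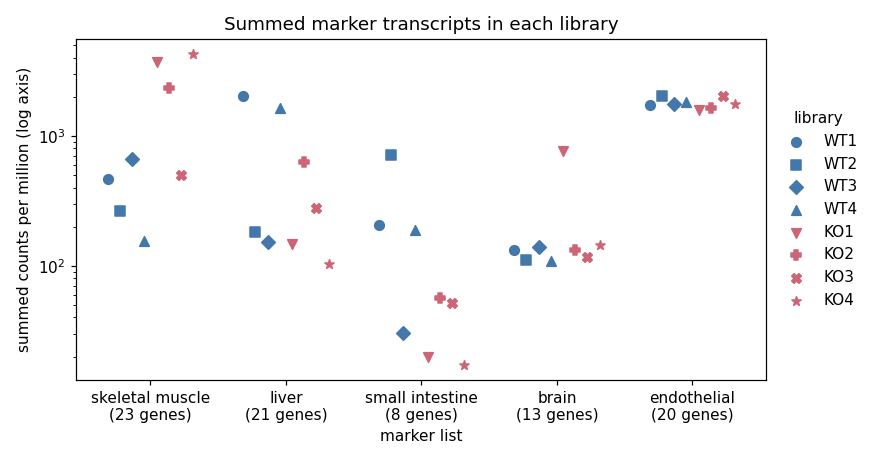
Summed CPM (log axis) of the marker genes of 5 tissues or cell types in each of the 8 libraries; each symbol is one library, coloured by label. Muscle markers lie between 2353 and 4243 CPM in KO1, KO2 and KO4, liver markers reach 2031 CPM in WT1 and 1630 in WT4, and brain markers 769.4 in KO1, while endothelial markers stay between 1570 and 2045.

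Thermogenic, beige, creatine and calcium cycling, nuclear-encoded respiratory chain and fatty acid oxidation genes did not pass as groups over all 8 libraries. Of 15 thermogenic adipocyte genes tested, 6 had positive and 9 negative log2 fold changes, with a median of -0.12. The list's camera adjusted p was 0.45, and 0.92 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Without KO3 the list passed as lower with the preset correlation (adjusted p = 0.018). Its most negative member, Slc27a2 at -1.86 ± 1.03, had 98 reads in WT1 and 79 in WT4, where liver markers were high. In the other libraries Slc27a2 had 4 to 29 reads. Cidea, a lipid droplet protein of brown fat, stood at 0.01 ± 0.38, Ppargc1a, a coactivator of mitochondrial genes, at 0.15 ± 0.25, Cpt1b at 0.62 ± 0.23 and Kcnk3 at -0.27 ± 0.15. Ucp1 and Dio2 were not analysed here. Tmem26 (2 to 11 reads) and Elovl3 (0 to 10 reads) lay under the count filter, so that differences in them were not detectable at this depth. The 8 beige markers had a median of 0.01 (adjusted p = 0.83), with Ear2 at 0.28 ± 0.34 (7 to 15 reads) and Sp100 at 0.12 ± 0.14. The 7 genes of creatine and calcium cycling had a median of 0.14 (adjusted p = 0.77), where the camera direction was down, with Pm20d1 at -0.69 ± 0.27 and Ryr2 at -0.35 ± 0.21. The 77 nuclear-encoded respiratory chain genes had a median of -0.04 (camera adjusted p = 0.22, and 0.92 with an estimated correlation). With the preset correlation they passed as lower without WT1 (adjusted p = 0.00039), KO1 (0.00054) or KO3 (0.024). Uqcrq had -0.29 ± 0.16 and Cox6a1 -0.29 ± 0.16. The 26 genes of fatty acid oxidation had a median of -0.05 (adjusted p = 0.66), with Acaa1b at -0.53 ± 0.17, and -0.33 without WT4.

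Mitochondrially encoded genes passed camera with a preset correlation as higher. Of 13 members, 12 were positive, with a median of 0.14 (adjusted p = 0.032; adjusted p = 0.92 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. mt-Atp6 had 0.26 ± 0.17, mt-Co3 0.16 ± 0.14, mt-Nd6 0.16 ± 0.14 and mt-Nd4l 0.20 ± 0.18. Without WT2, mt-Nd4l was 0.079, and without WT4, mt-Nd6 was 0.082. With skeletal muscle markers as a covariate, mt-Atp6, mt-Nd6 and mt-Nd4l turned to -0.176, -0.075 and -0.283. Without KO1, KO2 and KO4, which leaves KO3 as the only library labelled KO, mt-Atp6 and mt-Nd4l turned to -0.08 and -0.102. The group no longer passed camera without KO1 (adjusted p = 0.057), KO2 (0.18), KO4 (0.13), WT2 (0.47) or WT4 (0.32). The AMPK pathway, which senses cellular energy, had 13 of 16 positive members and a median of 0.17 (adjusted p = 0.0036; adjusted p = 0.32 with an estimated correlation), again with 0 members past either adjustment; it passed with each library left out (adjusted p from 0.0043 to 0.035). Prkaa2, a catalytic subunit of AMPK that is abundant in muscle, had 0.56 ± 0.20, Acacb 0.40 ± 0.20, Camkk2 0.23 ± 0.13 and Prkab2 0.33 ± 0.19, which was 0.19 without KO2 and -0.041 without KO1, KO2 and KO4. Prkaa2 was at 15.6 CPM in KO3 and between 23.7 and 25.5 CPM in KO1, KO2 and KO4, the libraries with high muscle sums.

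Lipid and hormone genes had small values. The 23 genes of beta-adrenergic signalling and lipolysis had a median of 0.04 (camera adjusted p = 0.45), with Adrb3, the main beta-receptor of fat, at 0.43 ± 0.27, and 0.21 without WT1. The 18 genes of de novo lipogenesis had a median of 0.00 (adjusted p = 0.92), with Mlxipl at 0.38 ± 0.17 and Fasn, the fatty acid synthase, at -0.03 ± 0.50. The 23 insulin signalling genes had a median of 0.03 (adjusted p = 0.51), with Grb14 at -0.54 ± 0.16 and Grb10 at 0.34 ± 0.18, and 0.18 without KO2. The 11 genes of class IIa HDACs and MEF2, targets of protein kinase D signalling, had 9 positive members and a median of 0.15. Their camera adjusted p was 0.097, and 0.92 with an estimated correlation. With the preset correlation they passed as higher without KO1 (adjusted p = 0.033). Mef2d had 0.24 ± 0.11 and Mef2c 0.31 ± 0.15. Cebpa, Pparg, Lep, Scd1, Fabp4 and Slc2a4 had -0.04 ± 0.22, 0.14 ± 0.16, -0.47 ± 0.33, -0.01 ± 0.16, 0.10 ± 0.16 and 0.01 ± 0.14. Without WT1 the value of Lep was -0.24 and without KO4 -0.74; Pparg was 0.04 without WT2 and Fabp4 0.01 without WT4. The signs of Cebpa, Scd1, Slc2a4, Fasn and Grb10, and of Cidea, Ppargc1a, Kcnk3, Adipoq, Pkd1 and Prkd3 above, turned under other settings.

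Cholesterol synthesis, matrix and immediate early genes passed camera with a preset correlation as lower, each with 0 members past either adjustment. Cholesterol synthesis had 17 of 23 negative members and a median of -0.15 (adjusted p = 0.0026; adjusted p = 0.92 with an estimated correlation), with Tm7sf2 at -0.33 ± 0.19 and Ebp at -0.23 ± 0.15. Fibrillar and basement membrane matrix had 26 of 31 negative members and a median of -0.17 (adjusted p = 0.0018; adjusted p = 0.92 with an estimated correlation). Its members Mmp14, Col5a2 and Sparc had -0.37 ± 0.13, -0.40 ± 0.16 and -0.41 ± 0.18, and Eln, elastin, had 0.54 ± 0.24. Without KO1 neither cholesterol synthesis (adjusted p = 0.49) nor matrix (0.13) passed, and without WT3 cholesterol synthesis did not (0.09). Immediate early genes had 17 of 19 negative members and a median of -0.19 (adjusted p = 0.016; adjusted p = 0.92 with an estimated correlation). Junb, Btg2, Fos and Zfp36 had -0.64 ± 0.27, -0.41 ± 0.18, -1.21 ± 0.61 and -0.47 ± 0.28, and Fos and Junb were highest in WT2, at 34.8 and 64.5 CPM. Without WT2 these values were -0.27, -0.29, -0.38 and -0.14 and the group did not pass (adjusted p = 0.74); it did not pass without KO1 (0.075), KO3 (0.065) or KO4 (0.052) either.

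Progenitor and fibroblast markers passed camera with a preset correlation as higher, with 12 of 17 positive members and a median of 0.24 (adjusted p = 0.049; adjusted p = 0.92 with an estimated correlation) and 0 members past either adjustment. Anxa3 had 0.59 ± 0.20, Sfrp4 0.93 ± 0.34, Thy1 0.45 ± 0.20 and Pi16 0.50 ± 0.23. Without KO2, Anxa3, Sfrp4 and Pi16 fell to 0.32, 0.63 and 0.32, and without KO1, Thy1, which is also a brain marker, fell to 0.23. Without KO1, KO2 and KO4, which leaves KO3 as the only library labelled KO, Sfrp4 and Thy1 turned to -0.292 and -0.015. The group did not pass camera without KO2 (adjusted p = 0.25), KO4 (0.19), WT1 (0.14), WT3 (0.06) or WT4 (0.21). The summed CPM of the list was 10700 ± 1730 in libraries labelled WT and 8880 ± 1490 in those labelled KO (SD, n = 4; exact permutation p = 0.257), but Gsn made up between 72% and 84.6% of it; without Gsn the sums were 1790 ± 177 and 1870 ± 221 (exact permutation p = 0.514). Of 6 inflammatory cytokines tested, 1 fell adjusted over the list alone and 0 over all genes. The 1 was Ccl7 at -1.28 ± 0.34, on 5 to 26 reads (adjusted p = 0.91 over all genes in the quasi-likelihood test). Il33 had 0.48 ± 0.34, and 0.20 without KO2. Its value was -0.429 with skeletal muscle markers as a covariate and -0.549 without KO1, KO2 and KO4. The list's median was 0.12 (camera adjusted p = 0.77, direction down). Of 4 B cell markers tested, 1 fell adjusted over the list alone, Ighm. The sum of the B cell list was also taken without Ebf1, its most abundant gene. It was 143 ± 28 CPM in libraries labelled WT and 97.6 ± 8.41 in those labelled KO (SD, n = 4). The exact permutation p was 0.0286, the smallest that 4 against 4 can give and not adjusted for the other sums. Ighm was the most abundant gene of this sum, at 83.4 ± 27.2 and 44.5 ± 8.37 CPM. The sum thus largely repeats Ighm, which was chosen for its small p, and is no separate result on B cells. The other 19 lists tested had medians between -0.35 and 0.22 and a smallest camera adjusted p of 0.14. With 1 library left out, some of them passed: cytosolic ribosomal proteins as lower without WT1 (adjusted p = 0.025), WT3 (0.0087) or KO1 (8.8e-06), erythroid genes as lower without WT2 (0.035), WT3 (0.042) or KO1 (0.0088), macrophage markers as lower without WT4 (0.041), neutrophil and mast cell markers as higher without WT2 (0.022), and glucocorticoid and circadian genes as higher without KO3 (0.018). Of 39 lists, 7 passed with a preset correlation, 0 with an estimated one and 0 by fry.

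**Figure D4:**
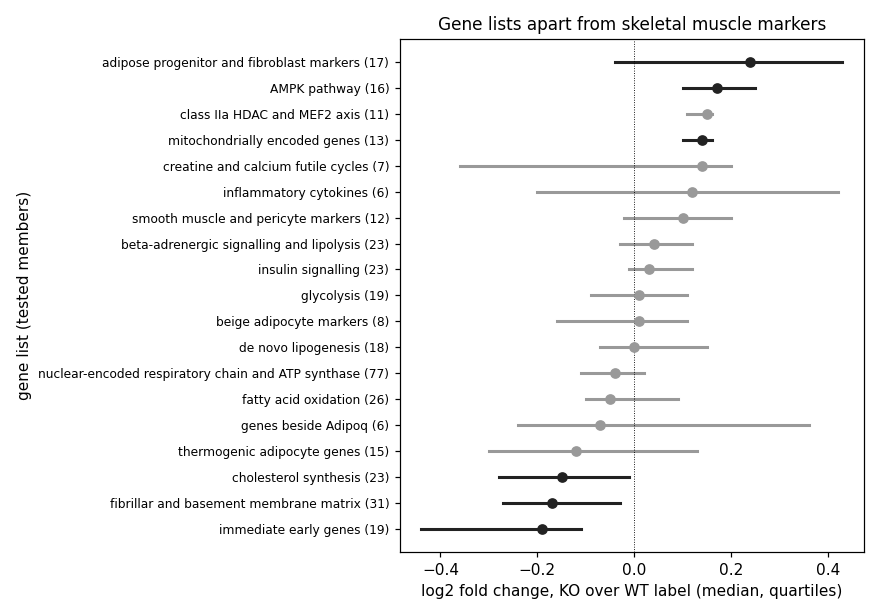
Median log2 fold change (points) and quartiles of members (lines) of the gene lists described, apart from skeletal muscle markers, for libraries labelled KO over those labelled WT; black marks lists past a camera adjusted p of 0.05 with a preset correlation, grey the others, and numbers in brackets are tested members. Medians lie between -0.19 and 0.24.

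The authors' deposited table holds more calls. The authors' deposited table lists 436 genes at an adjusted p under 0.05, 178 of them lower and the others higher in the libraries labelled KO. An edgeR exact test with one common dispersion over all genes gave the same 436 genes, with log2 fold changes that differed from the authors' deposited table by at most 4.6e-08. Of the 436, the groups did not overlap for 65, or 14.9%; the 2.86% that chance gives holds for genes not chosen by their difference, so it is no baseline for these. The genes include 22 of 23 skeletal muscle markers and 11 of 13 brain markers among those higher, and 21 of 21 liver and 7 of 8 small intestine markers among those lower. For 186 of its higher genes, KO3 lay inside or below the range of the libraries labelled WT. KO1 was the highest library for 187 of its higher genes and WT1 for 112 of the 178 lower genes, and 1 library held over 50% of all reads for 101 of the 436. In the quasi-likelihood fit, 110 of the 436 were at an unadjusted p under 0.05 and 211 were not tested.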

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

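The tests of explanations for the tissue transcripts, the muscle transcripts and Eif4a2, and the count of splits for genes without overlap, were chosen after the values were seen. Of 188 groups of 4 libraries examined, over the genes chosen by the naming rule and the marker sums, 9 held a library far from the other 3, measured as its gap to the nearest over the range; chance gives about 9.4.

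Among genes, Adrb3 was low in WT1 (gap 0.916 of the range; 121.6 CPM against 282.2 to 297), Acaa1b high in WT4 (0.854; 98.9 against 57.8 to 63.7), Anxa3 high in KO2 (0.943; 106.7 against 56.5 to 59.4) and Junb high in WT2 (0.831; 64.5 against 27.0 to 33.3). Among marker sums, the mammary epithelium and milk list was low in KO3 (0.844; 1099 CPM against 1553 to 1637), where Trf, transferrin, makes up between 94.3% and 97.4% of the sum in every library; without it KO3 had 61.5 CPM against 58.4 to 87.1. The 3 genes listed as mesothelial were high in WT2 (0.852; 16.2 against 5.10 to 6.75) and in KO1 (0.898; 45.5 against 3.90 to 8.13), through single genes that other tissues express: Krt19, of epithelia, with 28 reads in WT2, and Gpm6a, of neurons, with 122 reads in KO1. Schwann cell and nerve markers were high in KO1 (0.899; 820.8 against 381.6 to 426), with Mbp, which brain also expresses, at 838 reads, and so were brain markers (0.96; 769.4 against 117.6 to 143.4).

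Liver, small intestine and brain transcripts stood out in a few libraries of both labels. In KO1 the 13 brain markers lay at a median log2 difference of 3.64 above the other libraries (Snap25 190 reads against 1 to 11, Slc1a2 277 against 0 to 26), the 21 liver markers at 3.27 in WT1, 3.11 in WT4 and 1.55 in KO2 (Alb 2698, 2105 and 904 reads against 124 to 436), and the 8 small intestine markers at 3.08 in WT2 (Apoa4 1084 reads against 0 to 105). Depth or scaling is argued against: in unscaled reads the markers still lay 3.73, 3.39, 3.23 and 3.06 higher in KO1, WT1, WT4 and WT2, while the median of all tested genes differed by at most -0.14 (WT2). RNA or reads of another tissue in these libraries is a candidate explanation, where 2 of the liver, 1 of the intestine and 3 of the brain markers had at least 10 reads in every library, and 3, 0 and 2 are in lists fixed earlier; whether they entered at dissection, library preparation or sequencing was not tested. The label alone does not give the liver pattern. The liver sums were 2031 and 1630 CPM in WT1 and WT4, but 183.1 and 153.7 in WT2 and WT3. KO2, at 627.5 CPM, lay above WT2 and WT3. A further effect of the genotype on liver transcripts cannot be told apart from RNA or reads of another tissue (exact two-sided permutation p = 0.286). With values this far apart, 4 libraries per label are too few.

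Skeletal muscle transcripts were high in KO1, KO2 and KO4, while in KO3 their sum and Acta1 lay inside the range of the libraries labelled WT (Acta1 1649, 1096 and 1238 reads against 173 in KO3 and 27 to 205 in those labelled WT), as did 19 of the 23 markers, with 4 above it. A single muscle RNA source shared by the libraries is argued against: the ratio of Myh4 to Myh1 reads, myosins of different fast fibres, was 1.03 in KO1, 0.294 in KO2 and 3.04 in KO4, a 10.4-fold range. Muscle RNA that entered samples separately is a candidate explanation. The 23 markers moved together over the 8 libraries, with a median correlation of 0.972 between a marker and the mean of the others. Any cause that raises these markers in the same libraries gives such a correlation, so it does not decide between causes. Of the 23 markers, 5 had at least 10 reads in every library and 1 is in another list. An effect of the genotype on muscle genes cannot be told apart from a difference in dissection (exact two-sided permutation p = 0.0571), because the high libraries all carry 1 label.

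Eif4a2 was higher in each library labelled KO than in any labelled WT, including KO3. Muscle RNA is argued against, since the log2 fold change was 0.85 ± 0.21 (SE) with the muscle markers as a covariate. Reads of Rfc4, which overlaps its end, are argued against too, since Rfc4 rose by 1.6% as many reads as Eif4a2. Extra copies of the region beside Adipoq, as a transgene made from it could bring, cannot be told apart from an effect of the deletion. Rfc4 had a log2 fold change of 0.49 with a 95% interval from -0.25 to 1.22 on 6 to 18 reads, too few to decide. Overlapping genes were each given the shared reads, so some reads of Rfc4 may also be those of Eif4a2. Kng2 and Adipoq, which have more reads, had 95% intervals from -0.63 to 0.06 and from -0.54 to 0.29, below that of Eif4a2 (0.46 to 1.04). The Cre line and the genes that such copies would hold are not given in the sources used here, so these values do not decide. An effect of the deletion itself was not tested.

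Other splits of the 8 libraries into 4 and 4 do not allow chance to be excluded for the counts above 0 that follow. Counts from DESeq2, the likelihood ratio test, the surrogate variable fit and fits that leave out libraries were not compared over splits. The 0 genes at an adjusted p of 0.05 in the quasi-likelihood fit are reached by all 35 splits whatever the data, so that comparison decides nothing; the highest other split gave 270. At an unadjusted p under 0.05, 15 of 35 gave as many as the 653 (highest other 2765), and for genes without overlap 14 of 35 as many as the 424 (highest other 1711). For gene lists, 27 of 35 gave as many as the 7 (highest other 14). For the exact test with one common dispersion, 3 of 35 gave as many as the 436 (highest other 513), with a median of 246.5 over the others. The split with 270 calls sets WT1, WT3, KO2 and KO4 against the rest and points to a structure of the samples that does not follow the labels. Picked after the values were seen, the Y-linked gene Ddx3y had 239 to 291 reads in those libraries and 124 to 178 in the rest. Lpl had 20672 to 23409 reads in those libraries and 10023 to 14768 in the rest. What the structure is was not tested.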

How the results depend on the processing

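Fits with a common dispersion, without WT2 and KO1, and without KO1, KO2 and KO4 were chosen after the data were seen; in the last, KO3 alone is assumed to vary like the others. The counts of 0 genes higher and 0 lower (653 at an unadjusted p under 0.05) were unchanged in edgeR's quasi-likelihood fits with other scaling or filters, without the robust option, at an adjusted p of 0.1, with lymphoid or muscle covariates, and without WT2 and KO1 or KO1, KO2 and KO4, and in limma-voom; at an unadjusted p these settings gave from 499 genes (muscle covariate) to 873 (no filter). They moved with DESeq2 (45 higher, 6 lower; 11 list members; 47 shared with the authors' deposited table; 1085 genes had no adjusted p), the likelihood ratio test (30, 4; 9; 32), 1 surrogate variable (1 higher, 0 lower; 1; 1) and the exact test with one common dispersion (2.6e+02, 178; 49; 436 in all). With each library left out, genes higher ranged from 0 to 50, genes lower from 0 to 0, list members from 0 to 10 and genes shared with the authors' table from 0 to 50; only the fit without KO3 gave any. Apart from the common dispersion, which ignores that genes differ in spread, the cause was not tested. Gene lists shifted numbered 7, and 3 with the muscle covariate, 0 with an estimated correlation, 0 by fry, 17 without KO1, KO2 and KO4, and 4 (without KO4) to 9 (without KO3) with a library left out.

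The replicate numbers did not pair the libraries: same-numbered libraries correlated at -0.144, -0.291, -0.194 and -0.268 in their deviations, and no library correlated best with its own number. With the replicate block 0 genes were higher, 0 lower, and 6 lists shifted.

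Of 1628 values of genes chosen by the naming rule, Prkd1 apart, 1539 kept their sign and side of the threshold, 34 passed it and 55 turned sign. The cause was not tested. With DESeq2 and with the likelihood ratio test, Eif4a2, Mb, Adssl1, Zfp949, Cldn15, Htra1, Ighm, Apoc2, Pfkm, Eno3, Des, Myh2 and Myh1 passed the threshold. Without KO3, Mb, Adssl1, Pfkm, Eno3, Des, Myh2 and Myh1 passed it, and with 1 surrogate variable Eif4a2 did. Log2 fold changes turned with upper quartile factors (Pkd1 -0.002, Slc2a4 -0.001), no filter (Pkd1 -0.001), limma-voom (Pkd1 -0.039, Cidea -0.019, Slc2a4 -0.005), the replicate block (Cidea -0.009) and the lymphoid covariate (Pkd1 -0.005, Slc2a4 -0.111). With the muscle covariate they were Prkd1 -0.105, Cebpa 0.416, Adipoq 0.028, Scd1 0.108, Kcnk3 0.03, mt-Atp6 -0.176, mt-Nd6 -0.075, mt-Nd4l -0.283 and Il33 -0.429. Without WT2 and KO1 they were Pkd1 -0.017, Cebpa 0.106, Fasn 0.11 and Scd1 0.027. Without KO1, KO2 and KO4 they were Prkd1 -0.022, Cebpa 0.352, Adipoq 0.139, Slc2a4 -0.032, Kcnk3 0.085, mt-Atp6 -0.08, mt-Nd4l -0.102, Grb10 -0.083, Prkab2 -0.041, Sfrp4 -0.292, Thy1 -0.015 and Il33 -0.549. Over single libraries left out, ranges were Prkd1 -0.024 to 0.145, Prkd3 -0.013 to 0.187, Pkd1 -0.043 to 0.085, Cidea -0.346 to 0.225, Ppargc1a -0.065 to 0.289, Cebpa -0.201 to 0.164, Fasn -0.489 to 0.227, Scd1 -0.096 to 0.043 and Slc2a4 -0.121 to 0.072. Depth limits Tmem26, Elovl3, Rfc4 and Ear2, with at most 18 reads in a library. Lmod1 (12 to 23 reads) and Ccl7 (5 to 26 reads) lay little above this. A sex covariate was not run, since Y-linked genes had reads in all 8 libraries.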

Other observations

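Summed endothelial markers differed between labels by less than the spread between libraries of a label, at 1840 ± 141 CPM in libraries labelled WT and 1750 ± 210 in those labelled KO (SD, n = 4; exact two-sided permutation p = 0.486). Of the macrophage list, Lpl, which adipocytes also express, made up between 67.1% and 83.1% of the sum; without it the sums were 1650 ± 232 and 1580 ± 144 CPM (exact permutation p = 0.714). The T cell list had few reads, with Cd3e between 6 and 9 reads in libraries labelled WT and between 1 and 3 in those labelled KO, and its sum of 114 ± 10.5 and 106 ± 9.49 CPM came in large part from Cd247, between 26.5% and 47%, and from Thy1, so it says little about T cells. Haemoglobin and other erythroid genes ranged from 312 CPM in KO4 to 1393 in WT4, with a median log2 fold change of -0.35 over 5 tested members (camera adjusted p = 0.14).

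Leptin and lipid genes of adipocytes varied between libraries of 1 label. Lep, the hormone leptin, had 2639 reads in KO1, 3328 in KO3, 3903 in WT2 and 4975 in WT4, and between 5677 and 9041 in the other libraries. Fasn had 3986 reads in KO1 and 18210 in KO4. Lpl, the lipoprotein lipase, was chosen after its values were seen. It had 10023 reads in WT2, 11670 in KO1, 12713 in KO3 and 14768 in WT4, and between 20672 and 23409 in the others. Lep and Lpl thus divided the libraries as the split that sets WT1, WT3, KO2 and KO4 against the rest. Fasn did not, with 10973 reads in WT4 and 6885 in WT1.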
